A study of Listeria monocytogenes with 18 samples.

How the data were processed

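RNA sequencing libraries were analysed from a cocktail of 4 *Listeria monocytogenes* strains. Per the labels' protocols, the strains were grown at 37 °C in tryptic soy broth, spread as lawns on tryptic soy agar, harvested in buffered peptone water and combined in equal parts, and the sessile cells were resuspended in a sanitizer or in molecular grade water. The exposure lasted 70 s, of which 10 s were mixing and 60 s centrifugation. The sanitizers were chlorine at 5 ppm, peracetic acid at 5 ppm, lactic acid at 0.2% and silver dihydrogen citrate at 50%. Total RNA was extracted with a column kit and prepared with a stranded total RNA kit that depletes ribosomal RNA, per the labels' protocols. Of the 18 libraries, 4 each came from water, lactic acid, peracetic acid and silver dihydrogen citrate, and 2 from chlorine. The labels call the replicates biological, and the series' design text speaks of 4 biological replicates, of which 2 chlorine libraries were analysed here.

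Per the submitters' processing notes, FastQC, Salmon 1.10.2 and DESeq2 1.44.0 were used. Per the file headers, the deposited tables are salmon output with an estimated count and a TPM value for each feature, and the TPM values are scaled by effective length over all features. The estimated counts were the input of every test, after rounding to whole numbers. Of the features in a library, 0.563 to 2.42% had a fractional estimated count. The TPM values served 1 other setting, as log2(TPM + 1). The reference sequences, the trimming and the salmon options are not given in the sources used here, so overlapping features and near-identical copies (ribosomal RNA in particular) are treated as uncertain. All 3019 features matched a locus tag in a gene table of the EGD-e assembly, which was used for names, classes and neighbours only, because the deposited tables name no build. They comprise 2866 coding features, 9 ribosomal RNAs, 45 transfer RNAs, 96 other non-coding RNAs and 3 further RNA entries that share a tag with one of these.

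Total counts ranged from 1026099 to 28898808 per library, but a pair of non-coding RNAs took most of them, and the coding features together held 3639 to 107109 counts. A count of 0 allows a share of up to 0.00280% of the coding counts in the deepest library and 0.0824% in the shallowest, at 3 counts per library. These limits cover counting error only, since amplified reads are not independent molecules. The difference between length and effective length in the deposited tables sorts the libraries into 6 with short fragments (water replicates 1 to 3, both chlorine libraries and peracetic acid replicate 3) and 12 with longer ones, with the boundary at 150 bases. No pair of libraries within a group agreed within sampling noise.

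Features were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust estimation, two-sided test, TMM factors) in 1 fit of all 18 libraries with the group as the only term, so that the groups share an estimate of the spread. Features were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 1436 features, 1346 of them coding. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Every sanitizer was compared with water and with each of the others. Levels are given in CPM computed from the deposited counts with the TMM factors, as mean ± SD over the libraries, and fold changes are log2 values ± standard error. That standard error is the absolute log2 fold change divided by the square root of the test's F statistic, so it follows from the test. Where all libraries of a group had 0 counts, the fold is given as a lower bound against 3 counts over the group, because the fitted value then depends on edgeR's prior count of 0.125. Library measures were compared with exact two-sided permutation tests, adjusted over the 72 tests of that family.

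The designs, the rule for named features, the gene lists and most of the other settings tried were fixed before the data were examined. For each sanitizer against water, the rule takes the 8 largest rises and 8 largest falls among called features that average at least 10 CPM and lie on 1 side of every water library. Where fewer than 5 features pass, it takes all of them and the 5 with the smallest p. It adds up to 2 members of every gene list with the smallest p, and in every contrast sigB, dnaK, groEL, clpB, recA, kat, sod, fri, hly and flaA. The abundant RNAs, the features called between sanitizers and the features called only under an alternative were named after their values were seen.

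Of 26 gene lists, 25 were matched by locus tag or symbol, and 6 list members were moved to the tag that carries their symbol. The list of phosphotransferase components, defined by product name, could not be matched because no product names were used here. Lists with at least 5 tested members (17 of them, 68 tests) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The other 8 lists had fewer tested members and are described by value. A count called adjusted over the list alone applies the Benjamini-Hochberg adjustment to the members only.

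The fit was tested on simulated data with known fold changes before use. Correlations of fold changes between sanitizers were set beside 20 simulations of unchanged groups. In each, all 18 libraries were redrawn from common means, and the redrawn water libraries were shared by all contrasts. The correlations were repeated with the water libraries split between the sanitizers. Other settings, chosen in advance, were RLE factors, library totals, no filter, a filter at 10 CPM, DESeq2 1.42.0, limma-voom, a fit of the groups compared only, a minimum log2 fold change of 1, leaving out the 10 most abundant features, the replicate number as a block, TPM values, and leaving out each library in turn. Alternatives added after the data were seen were the fragment length class as a term, libraries of 1 class only, coding features only, libraries with at least 10000 coding counts only, shares outside the most abundant pair of RNAs, lower bounds with each library left out in turn (normalization factors held), and counts at an unadjusted p over other splits of the libraries.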

Results

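The libraries measure the transcriptome of sessile *L. monocytogenes* cells, as a pool of 4 strains, after 70 s in chlorine, lactic acid, peracetic acid or silver dihydrogen citrate, with cells in molecular grade water as the background. Silver dihydrogen citrate is a solution of silver ions held by citric acid, chlorine and peracetic acid are oxidants, and lactic acid is a weak organic acid. The water libraries held 28898808, 15114474, 12212878 and 6070261 counts, and the chlorine libraries 20087191 and 23726383. The lactic acid libraries held 8791060, 4903818, 2517261 and 4918634 counts. The peracetic acid libraries held 9445566, 8837661, 11747275 and 6029129. The silver dihydrogen citrate libraries held 2934684, 4707718, 3582662 and 1026099. Coding features received 42268 ± 19741 counts per water library (SD, n = 4), 39170 ± 28669 after chlorine (n = 2), 11512 ± 4914 after lactic acid, 35719 ± 12039 after peracetic acid and 36026 ± 48657 after silver dihydrogen citrate (n = 4 each).

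The first question was which RNAs made up the libraries and whether this makeup differed from water. The non-coding RNA lmos95 took 77.8% ± 2.44 of the counts in water (SD, n = 4), 82.6% ± 9.62 after chlorine (n = 2), 82.0% ± 7.65 after lactic acid, 83.1% ± 5.32 after peracetic acid and 49.0% ± 14.3 after silver dihydrogen citrate (n = 4 each). The non-coding RNA lmos89 took 20.03% ± 2.73 in water and 34.8% ± 16.3 after silver dihydrogen citrate. A further one, lmos81, took 0.315% ± 0.247 in water, 0.783% ± 0.312 after lactic acid and 10.2% ± 17.2 after silver dihydrogen citrate, where replicate 1 reached 36.0% and the lowest library stood at 0.669%. The share of lmos53 was 0.471% ± 0.0290 in water and 1.39% ± 0.642 after silver dihydrogen citrate. Outside lmos95 and lmos89, coding features made up 15.2% ± 9.44 of the counts in water, 10.95% ± 2.02 after lactic acid, 20.3% ± 5.07 after peracetic acid and 6.36% ± 2.89 after silver dihydrogen citrate. The coding share of all counts ran the other way in its mean, from 0.367% ± 0.325 in water to 1.22% ± 1.64 after silver dihydrogen citrate (0.102 to 3.65%, exact p = 0.400). All 4 silver dihydrogen citrate libraries lay below all 4 water libraries in the lmos95 share, the coding share outside the abundant pair and the total count, and above them in the lmos53 share. Each of these had an exact permutation p of 0.0286, the smallest that 70 regroupings can give, and so had the coding counts after lactic acid, but the adjusted p over 72 tests was 0.411. Water replicate 4, the 1 water library with long fragments like the silver dihydrogen citrate libraries, had lmos95 at 80.8% and coding features at 29.1% outside the abundant pair. With 1 such water library, these shares were not tested within the class, and lmos95 overlaps the coding feature lmo2711.

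**Figure D1:**
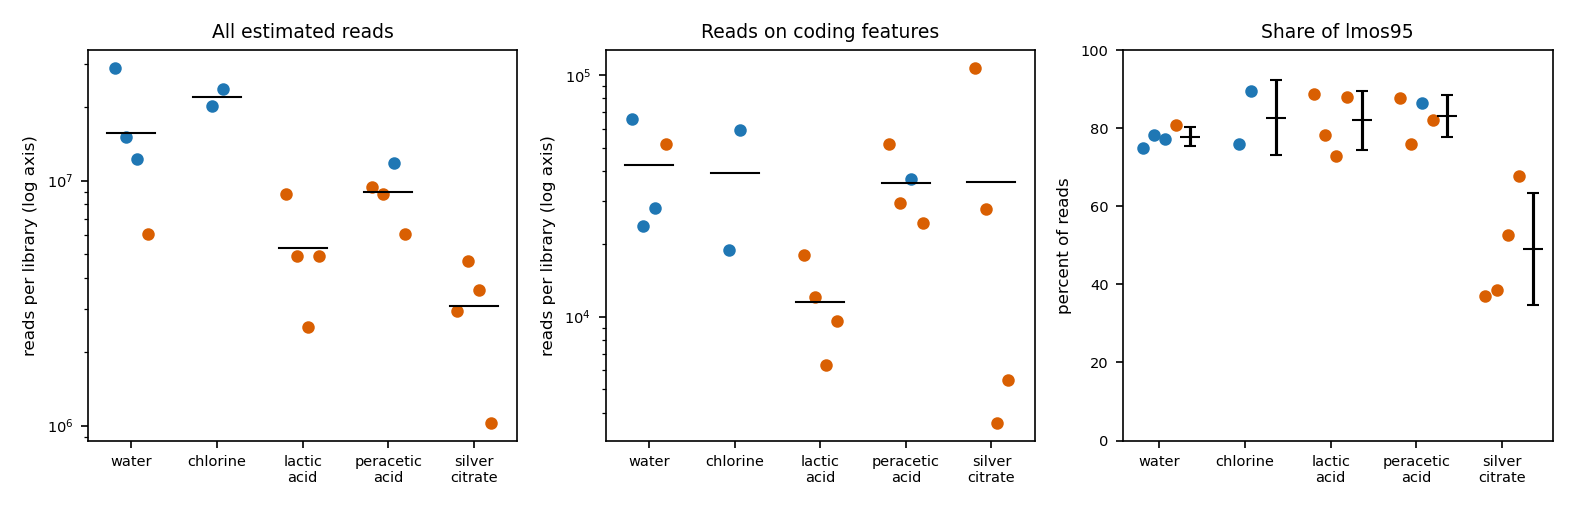
All counts per library (log axis), counts on coding features (log axis) and the lmos95 share (percent) in each group. Dots are libraries, coloured by fragment length class, and black marks are means, with SD on the linear axis; the lmos95 share averaged 77.8% in water and 49.0% after silver dihydrogen citrate.

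The remaining questions were asked gene by gene, with low power. The 1436 features tested had a median of 2 counts per library, 42.3% of their values were 0, and the common biological coefficient of variation was 1.63. Of 1436 features simulated, 1137 passed the filter, and only changed features among these enter the following shares. Changed features lost to low counts are left out, so recovery over all changed features is no higher. The same fit recovered 36.8% of 64-fold changes by silver dihydrogen citrate, 39.3% by lactic acid, 37.5% by peracetic acid and 3.92% by chlorine. Of 4-fold changes it recovered 0% by silver dihydrogen citrate and chlorine, 1.89% by lactic acid and 6% by peracetic acid. Among simulated genes at 10 or more CPM it recovered 4 of 5 64-fold changes by silver dihydrogen citrate, 2 of 2 by lactic acid, 3 of 5 by peracetic acid and 0 of 5 by chlorine, and of 4-fold changes 0 of 2, 0 of 6, 0 of 2 and 0 of 4. Depth, spread and the number of libraries were not separated as reasons. The median log2 fold change of all tested features was −0.18 after chlorine, −0.51 after lactic acid, 0.00 after peracetic acid and −0.09 after silver dihydrogen citrate. With library totals in place of TMM factors these medians were −0.99, −0.73, 0.31 and 2.00, and with RLE factors the lactic acid median was −0.17.

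Silver dihydrogen citrate was compared with water to ask which transcripts differed after exposure to silver ions. The small RNA lmos55 fell by 6.62 ± 1.12 on the log2 scale, from 37.0 ± 28.8 CPM in water to 0.499 ± 0.999 CPM (n = 4 each, adjusted p = 6.11e-06). The coding feature lmo0646 fell by 6.72 ± 1.48, from 11.9 ± 8.73 to 0.0580 ± 0.116 CPM (adjusted p = 0.00382). The coding feature lmo1423 fell by 3.83 ± 0.94, from 27.7 ± 7.04 to 1.81 ± 2.11 CPM (adjusted p = 0.0223). These were the only calls by edgeR, 0 higher and 3 lower, with 196 features at an unadjusted p under 0.05, where other splits of the same 8 libraries gave 92 to 196, while DESeq2 called 16 higher and 16 lower and limma-voom 13 higher and 16 lower. RLE factors gave 1 higher and 3 lower, and library totals 10 higher and 0 lower with none of these 3 among them. With the fragment length class as a term 0 features were called (103 at an unadjusted p under 0.05), with lmos55 at −5.34 ± 1.53 (adjusted p = 0.244), lmo1423 at −4.00 ± 1.11 (adjusted p = 0.244) and lmo0646 at −3.14 ± 4.50. In long-fragment libraries alone 0 were called (97 at an unadjusted p under 0.05), with 1 water library in that fit. There lmo1423 stood at −4.02 ± 1.39 and lmos55 at −3.23 ± 1.81, while lmo0646 is listed at 0 in that water library and had 6 counts after silver dihydrogen citrate, so that it was not lower.

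**Figure D2:**
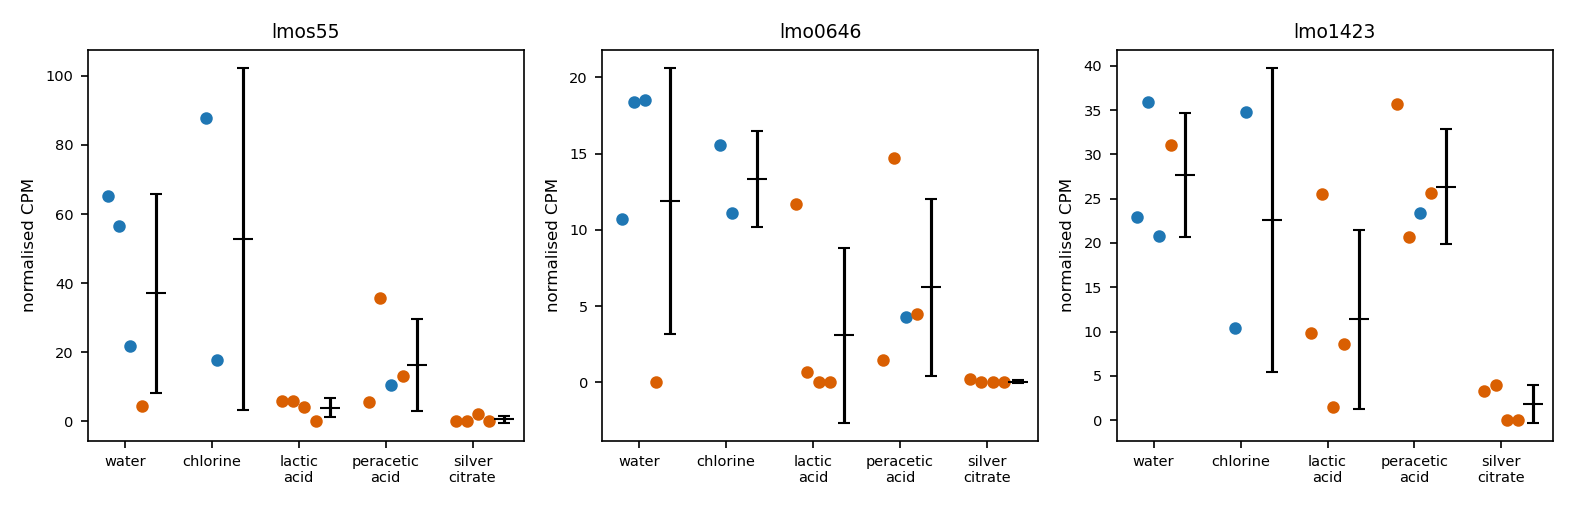
Normalised levels of lmos55, lmo0646 and lmo1423 (CPM) in the libraries of each group. Dots are libraries, coloured by fragment length class, and black marks are mean ± SD; in water the means were 37.0, 11.9 and 27.7 CPM, and after silver dihydrogen citrate 0.499, 0.0580 and 1.81 CPM.

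Features close to the threshold after silver dihydrogen citrate included lmo2677, at −3.49 ± 0.95 (adjusted p = 0.0814), and lmo1665, with 0 counts in water and at least 69.7-fold higher (adjusted p = 0.0892). Metal homeostasis was represented by lmo1853, listed as a copper exporter, with 180 counts in water and 0 after silver dihydrogen citrate, at least 51.2-fold lower (adjusted p = 0.236). It was the 1 of 7 tested members of the copper, zinc and manganese list that passed when adjusted over the list alone. The superoxide dismutase gene sod stood at 3.67 ± 1.52, with 6.88 ± 5.37 CPM against 0.518 ± 0.586 (adjusted p = 0.305), and DESeq2 called it at 3.77 (adjusted p = 0.00792). The ribosomal protein gene rplU stood at −2.63 ± 0.91 (adjusted p = 0.238), the teichoic acid D-alanylation gene dltA at −2.07 ± 0.89 and the ATP synthase gene atpD at −2.71 ± 1.21. The stress regulator gene sigB was at 0.62 ± 2.02, the disaggregase gene clpB at −2.37 ± 1.41, the recombinase gene recA at 2.18 ± 1.76, the catalase gene kat at −0.81, the chaperone genes dnaK and groEL at −0.67 and −1.11, the ferritin-like gene fri at 0.95 and the listeriolysin gene hly at 0.14, and none passed. The acid resistance member lmo0043, with 0 counts after silver dihydrogen citrate, was at least 28.99-fold lower and also passed only when adjusted over the list alone. Without silver dihydrogen citrate replicate 1 the bounds for lmo1853 and lmo0043 were 17.3-fold and 9.79-fold, without water replicate 4 that for lmo1853 was 27.4-fold, and without water replicate 2 that for lmo0043 was 15.5-fold. The bound for lmo1665 was 17.5-fold without silver dihydrogen citrate replicate 2 and 46.0-fold and 46.5-fold without water replicates 1 and 4. Without water replicate 2, water replicate 4 or silver dihydrogen citrate replicate 4, lmo1423 was no longer called and 2 features were, and the same held with no filter on low counts and in a fit of the groups compared only. Limma-voom called lmos55 and lmo1423 but not lmo0646. Without silver dihydrogen citrate replicate 1, 2 or 3, 10, 5 and 7 features were called.

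The comparison of chlorine with water asked which transcripts differed after a short exposure to this oxidant. The 16S ribosomal RNA entry lmor04 came closest to the threshold, at −4.11 ± 1.02, with 23.5 ± 1.02 CPM after chlorine (n = 2) against 406 ± 468 CPM in water (n = 4, adjusted p = 0.0860). The entry is uncertain because near-identical copies share its reads. The aminoacyl-tRNA synthetase gene proS, with 229 counts in water and 0 after chlorine, was at least 30.03-fold lower, and hisS, with 63 counts after chlorine and 0 in water, at least 33.6-fold higher (adjusted p = 0.863 for both). Other features with 0 counts in water were the cell division gene ftsE, at least 17.6-fold higher, and the stress kinase gene rsbT, at least 23.1-fold higher. The catalase gene kat had 58 counts in water and 0 after chlorine, at least 11.4-fold lower (adjusted p = 0.863), while sod stood at 2.48 ± 1.62, recA at 2.90 ± 2.00, groEL at 0.80 ± 1.93, dnaK at 0.31, clpB at −0.97 ± 1.70, sigB at 0.26 ± 2.46, fri at −0.65 and hly at 0.39. These bounds lean on single libraries. Without chlorine replicate 2 they were 7.88-fold for proS, 15.3-fold for hisS and 2.99-fold for kat, and ftsE kept 2 counts and no bound, as rsbT kept 3 without chlorine replicate 1. Without water replicate 4 the bound was 12.6-fold for proS, 22.4-fold for hisS, 11.7-fold for ftsE and 15.4-fold for rsbT, without water replicate 1 it was 22.2-fold, 11.6-fold and 15.3-fold for the last 3, and without water replicate 3 it was 2.87-fold for kat. The flagellin gene flaA could not be tested in any contrast, with 2 counts in 1 chlorine library and 0 in all others. Of 1436 features edgeR called 0, with 61 at an unadjusted p under 0.05. DESeq2 called 2 (lmor04 at −3.94 and the ribosomal RNA entry lmor09) and limma-voom 2 others (lmo0984 and lmo1232). The entry lmor04 was called without water replicate 4 (−4.33, adjusted p = 0.0235), within the short-fragment libraries (−4.38 ± 0.62, adjusted p = 3.84e-09) and when adjusted over the list of RNAs alone. The short-fragment fit holds water replicates 1 to 3, both chlorine libraries and peracetic acid replicate 3, so it also lacks water replicate 4.

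**Figure D3:**
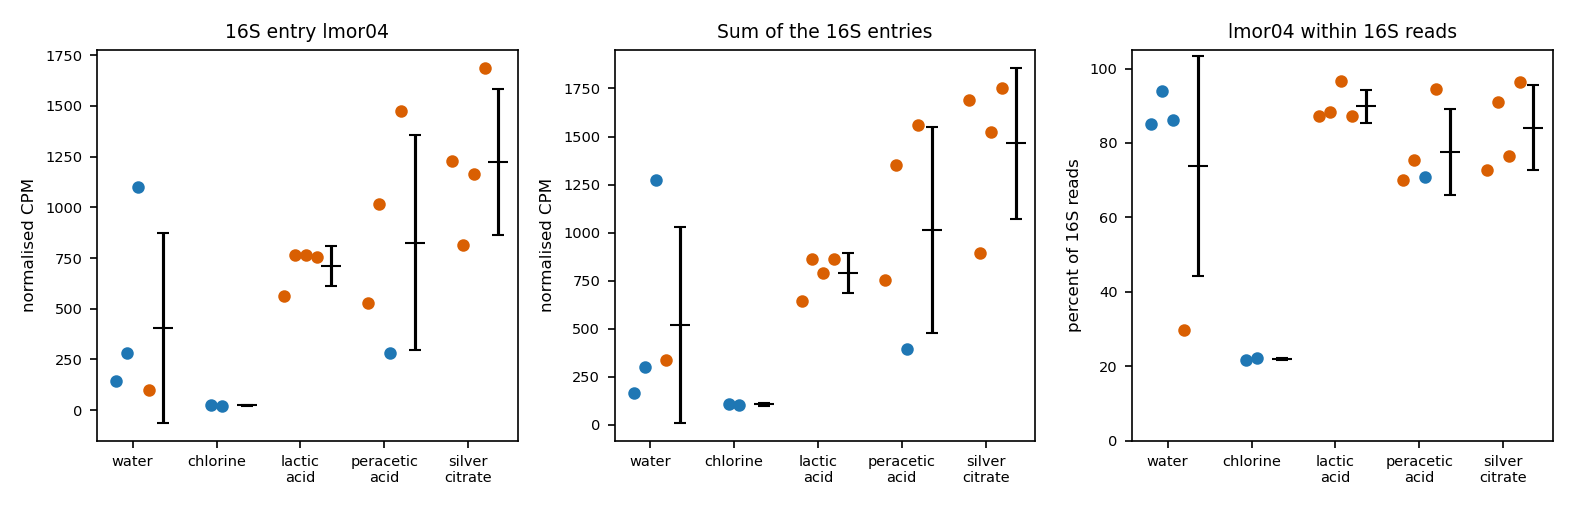
The 16S entry lmor04 (CPM), the summed 16S entries (CPM) and lmor04 as percent of the 16S counts in each group. Dots are libraries, coloured by fragment length class, and black marks are means, with SD on the linear axes; lmor04 averaged 23.5 CPM after chlorine and 406 CPM in water.

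Lactic acid was set against water to ask which transcripts differed in a weak acid. All lactic acid libraries have long fragments, as has water replicate 4 alone among the water libraries. The small RNA lmos55 stood at −3.23 ± 0.91, with 3.92 ± 2.74 CPM against 37.0 ± 28.8 (n = 4 each), and lmo1967, a member of the cell-envelope stress list, at −4.02 ± 1.20, with 0.873 ± 1.17 CPM against 14.9 ± 6.38. In water replicate 4 lmos55 was at 4.36 CPM and lmo1967 at 17.5 CPM. The mannose phosphotransferase gene lmo0783 had 242 counts in water and 0 after lactic acid, at least 33.0-fold lower, and lmo2665 had 210 and 0, at least 24.1-fold lower. The SigB regulon member lmo0515 stood at 6.41 ± 2.11, with 5.64 ± 3.53 CPM against 0.0588 ± 0.0790, and lmo0274 at −5.59 ± 1.77. The efflux genes lmo2087 and lmo0852, with 0 counts in water, were at least 36.2-fold and at least 10.1-fold higher, and the ribosomal protein genes rplE and rplF, with 0 counts after lactic acid, at least 13.1-fold and at least 10.9-fold lower. All of these had an adjusted p of 0.270. Of these bounds, that for lmo2087 was 7.51-fold without lactic acid replicate 3, lmo0852 had counts in lactic acid replicate 1 alone, rplE kept 3 counts and no bound without water replicate 1, and that for rplF was 6.05-fold without water replicate 2. Without water replicates 1 and 4 the bounds were 23.9-fold and 24.2-fold for lmo2087 and 6.64-fold and 6.70-fold for lmo0852. The protease gene clpC stood at −4.05 ± 1.72, the flagellar export gene fliP at −4.08 ± 1.83, the thioredoxin reductase gene trxB at 2.92 ± 1.66, sod at 2.52 ± 1.46, recA at 2.77 ± 1.81, hly at 1.87 ± 1.63, fri at 1.75, groEL at 0.79, clpB at −1.45, sigB and dnaK both at −0.63 and kat at −0.40 ± 2.06. Of 1436 features edgeR called 0, with 237 at an unadjusted p under 0.05, where other splits of the same 8 libraries gave 190 to 247, while DESeq2 called 9 higher and 4 lower and limma-voom 1 higher and 4 lower. With features at 10 or more CPM only, 1 was called, lmo1967 (−3.93, adjusted p = 0.0428). Adjusted over the list alone, lmo0783 passed in the mannose phosphotransferase list, lmo1967 in the envelope list, lmo2087 and lmo0852 in the efflux list, lmos55 in the RNA list and fliP in the flagellar list, of which it was the 1 tested member.

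Peracetic acid was compared with water in the same way, as another oxidant at 5 ppm. The feature lmo0493 had 95 counts in water and 0 after peracetic acid, at least 33.9-fold lower. For lmo0269, water replicate 2 held 64 counts, and the other water libraries and all peracetic acid libraries held 0. Its bound of at least 34.6-fold lower therefore rests on 1 water library. With 0 counts in water, lmo1461 was at least 37.9-fold higher, the ornithine carbamoyltransferase gene argF at least 32.7-fold, ftsE at least 29.9-fold, the ribosomal protein gene rplM at least 22.1-fold and lmo1665 at least 16.6-fold higher (adjusted p = 0.386 for each of these). Without 1 peracetic acid library the lowest bounds were 22.2-fold for lmo0493, 22.7-fold for lmo0269 and 7.87-fold for rplM (without replicate 1), 18.7-fold for argF and 12.3-fold for ftsE (replicate 2), 9.86-fold for lmo1665 (replicate 3) and 17.97-fold for lmo1461 (replicate 4). Leaving out water replicate 1 or 4 lowered the bounds of the features higher after peracetic acid by 1.514 or 1.501 times. Without water replicate 2, lmo0269 kept 0 counts and no bound. The prolipoprotein gene lgt stood at 5.16 ± 2.44 (adjusted p = 0.392), recA at 2.77 ± 1.80, sod at 2.19 ± 1.436, the peroxide regulator gene lmo1683 at 1.72 ± 1.505, fri at 1.21, groEL at 0.94, sigB at 0.33, clpB at −0.05, kat at −1.25, hly at −1.43 and dnaK at −1.50. Of 1436 features edgeR called 0, with 145 at an unadjusted p under 0.05, where other splits of the same 8 libraries gave 138 to 182, and DESeq2 and limma-voom also called 0. Adjusted over the list alone, argF passed among 6 tested members of the acid resistance list. The list gives this symbol to another locus tag, and the member was moved to lmo1587 by its symbol. It is therefore no result for the locus tag listed. Within the short-fragment libraries, which hold 1 peracetic acid library, 2 features were called lower (lmor15 and lmos97).

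Gene lists were tested to see whether members of a pathway moved together. The structural and regulatory RNAs were lower after peracetic acid, with 23 of 89 tested members higher and 65 lower than in water and a median of −0.55 (camera adjusted p = 0.00126). The adjusted p was 0.979 with an estimated correlation, and 0.562 with the fragment length class as a term. Within the list, transfer RNAs had 4 members higher and 30 lower (median −0.59), other non-coding RNAs 13 and 34 (median −0.65) and ribosomal RNAs 6 and 1 (median 0.67). After silver dihydrogen citrate the same list had 65 members higher and 24 lower (median 1.02, adjusted p = 0.129), with the transfer RNAs at a median of 1.07. Its medians after chlorine and lactic acid were 0.00 and −0.51 (−0.44 with undetected members at their bound). No other of the 68 tests passed, fry called 0 (smallest adjusted p = 0.979), and in 28 tests the median, the mean and the direction of the test differed in sign. These tests had low power: a simulated list of 17 tested members, raised 4-fold by silver dihydrogen citrate, gave an unadjusted camera p of 0.0781. Lists that did not pass are therefore not shown to be unchanged.

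Among the stress lists, the 94 tested members of the SigB regulon had medians of −0.13, −0.02, 0.26 and 0.17 after chlorine, lactic acid, peracetic acid and silver dihydrogen citrate, the order of sanitizers in every sentence here, and the first and the second of these were 0.00 with undetected members at their bound. None of the 5 tested heat-shock proteases of the CtsR list was above water after chlorine or lactic acid, with medians of −0.70, −1.45, −0.05 and −0.98 (lactic acid adjusted p = 0.212). The 12 oxidative stress genes had medians of 0.00, 0.41, 1.30 and −0.49, with 8 of 12 higher after peracetic acid (adjusted p = 0.629). The 11 SOS genes had medians of −0.23, −0.20, 0.34 and −0.55. The 7 thioredoxin and disulfide genes had medians of −0.48, −0.67, −0.14 and 0.86 (−0.43 and 0.00 at the bound for the first and the second). The 7 copper, zinc and manganese genes had medians of −1.78, −0.36, −0.09 and 0.50. The 6 acid resistance genes, with argF moved by its symbol among them, had medians of −3.30, −1.20, −0.43 and −0.13 (−2.06 at the bound after chlorine). After chlorine 5 of 6 were lower. The 22 cell-envelope stress genes had medians of −0.02, −0.14, −0.18 and 0.11.

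In central functions, the 44 ribosomal protein genes had medians of −0.03, −0.82, 0.04 and −0.21 (0.00 and −0.63 at the bound for the first and the second), with 28 of 44 lower after lactic acid. The 9 ATP synthase genes had medians of −0.48, 0.15, −0.16 and −0.33, with 7 of 9 lower after silver dihydrogen citrate. The 6 purine synthesis genes had medians of 0.14, 1.05, −1.04 and −0.72, and the 10 pyrimidine synthesis genes −0.79, −2.30, −0.30 and −0.29 (−0.41 and −1.24 at the bound for the first and the second). The 5 branched-chain amino acid genes had medians of −4.50, 0.17, −1.02 and −0.09 (−1.12 at the bound after chlorine). The 5 mannose phosphotransferase genes had medians of −0.12, 0.01, 0.52 and 0.51. The 7 tested genes of the propanediol, ethanolamine and cobalamin cluster had medians of 0.14, −1.28, 0.29 and −1.82 (−0.83 at the bound after silver dihydrogen citrate). The 16 genes of the monocin locus, a phage tail-like element, had medians of 0.46, −0.41, 0.57 and 0.26 (−0.01 at the bound after lactic acid). Lists with too few tested members for a test were the HrcA chaperones with 4 (medians 0.34, −1.07, −0.88 and −0.48), osmolyte uptake with 4 (0.66, 0.68, 2.05 and 1.25, the first being 0.82 at the bound) and fatty acid synthesis with 4 (−0.41, −1.24, −0.22 and −0.87). Multidrug efflux had 4 tested members (−0.02, 2.79, −0.60 and 1.75, with 1.62 and 0.43 at the bound for lactic acid and silver dihydrogen citrate) and the PrfA virulence genes 3 (−0.47, 0.16, 0.37 and −0.12). Iron and haem uptake had 2 (−0.50, −3.12, −0.58 and −0.19, with −1.25 at the bound after lactic acid), flagella and chemotaxis 1 (fliP, at −2.88, −4.08, −0.95 and −2.35), and the prophage list 0.

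The sanitizers were then compared with each other, which tests differences between them directly. The 16S entry lmor04 was higher after lactic acid than after chlorine by 4.92 ± 1.07 on the log2 scale (711 ± 98.3 against 23.5 ± 1.02 CPM, adjusted p = 0.00648), after peracetic acid by 5.13 ± 1.08 (825 ± 530 CPM, adjusted p = 0.00323) and after silver dihydrogen citrate by 5.70 ± 1.12 (1224 ± 360 CPM, adjusted p = 0.000253). The small RNA lmos55 was lower after silver dihydrogen citrate than after chlorine, at −7.13 ± 1.19 (adjusted p = 3.47e-06), and than after peracetic acid, at −5.42 ± 1.08 (adjusted p = 0.000739). The coding feature lmo0646 was lower in the same comparisons, at −6.89 ± 1.55 (adjusted p = 0.00419) and −5.79 ± 1.43 (adjusted p = 0.0290). Between peracetic acid and silver dihydrogen citrate, lmo1423 stood at −3.76 ± 0.94 (adjusted p = 0.0290), lmo0540 at −3.59 ± 0.94, with 2.61 ± 2.71 CPM after silver dihydrogen citrate against 33.0 ± 16.5, and lmos14 at 4.58 ± 1.20, with 24.2 ± 21.8 against 1.01 ± 0.783 CPM (adjusted p = 0.0416 for the last pair). Both chlorine libraries have short fragments and all lactic acid and silver dihydrogen citrate libraries long ones, so that these contrasts with chlorine are confounded with the fragment length class. With the class as a term, lmor04 stood at 5.15 ± 1.48 against lactic acid, 5.35 ± 1.36 against peracetic acid (adjusted p = 0.114) and 5.94 ± 1.49 against silver dihydrogen citrate, lmos55 at −5.78 ± 1.85 and lmo0646 at −3.28 ± 4.70, and edgeR called 0 features between chlorine and lactic acid, peracetic acid or silver dihydrogen citrate (73, 25 and 61 at an unadjusted p under 0.05). The 5 features called between peracetic acid and silver dihydrogen citrate were all called with that term, lmo0646 at −5.55 ± 1.45 (adjusted p = 0.0472). By edgeR with the group as the only term, 1 feature differed between chlorine and lactic acid, 1 between chlorine and peracetic acid, 3 between chlorine and silver dihydrogen citrate and 5 between peracetic acid and silver dihydrogen citrate. Between lactic acid and peracetic acid edgeR called 0 (207 at an unadjusted p under 0.05, DESeq2 2, limma-voom 1), and between lactic acid and silver dihydrogen citrate 0 (183 at an unadjusted p under 0.05, DESeq2 9, limma-voom 0). Without either chlorine library, 0 features differed between chlorine and lactic acid or peracetic acid, and without chlorine replicate 1, 0 differed between chlorine and silver dihydrogen citrate, without chlorine replicate 2, 2, and without silver dihydrogen citrate replicate 1 or 3, 5. Between peracetic acid and silver dihydrogen citrate, 1 differed without peracetic acid replicate 2, silver dihydrogen citrate replicate 4 or the filter on low counts, 2 without peracetic acid replicate 1, 3 or 4 or silver dihydrogen citrate replicate 3, and 10 without silver dihydrogen citrate replicate 1. Between peracetic acid and silver dihydrogen citrate, 1 higher and 4 lower became 3 higher and 4 lower with RLE factors and 6 higher and 0 lower with library totals. With library totals, chlorine against silver dihydrogen citrate changed from 1 higher and 2 lower to 2 higher and 0 lower, and lactic acid against silver dihydrogen citrate gave 6 higher and 0 lower.

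Whether the sanitizers shared a response was asked from the fold changes against water, across genes, which are not independent replicates. Over 1436 features the correlation was 0.530 between lactic acid and silver dihydrogen citrate, 0.519 between peracetic acid and silver dihydrogen citrate, 0.484 between lactic acid and peracetic acid, 0.402 between chlorine and lactic acid, 0.487 between chlorine and peracetic acid and 0.433 between chlorine and silver dihydrogen citrate. Simulated unchanged groups, with water redrawn too and shared by the contrasts, gave means of 0.458, 0.481, 0.476, 0.396, 0.405 and 0.404 in that order. The highest of the 20 simulations were 0.502, 0.523, 0.516, 0.465, 0.455 and 0.447. Lactic acid with silver dihydrogen citrate and chlorine with peracetic acid lay above their highest, and the other pairs below. The observed covariances were 4.17, 3.19, 3.47, 3.15, 2.97 and 2.91, against simulated ones of 2.63, 2.61, 2.68, 2.71, 2.62 and 2.66, so that the difference was largest for lactic acid and silver dihydrogen citrate, at 1.54. With the water libraries split between the sanitizers, that pair's correlation averaged 0.0994 and lay between 0.0873 and 0.113 over the splits. The averages of the other pairs lay near 0, from −0.0227 to 0.0282, and over the splits these pairs ran from −0.0666 to 0.0514. All lactic acid and silver dihydrogen citrate libraries have long fragments, and water replicates 1 to 3 short ones. The simulations held no effect of the fragment length class, and splitting the water libraries does not remove one. For lactic acid and silver dihydrogen citrate a class effect can therefore not be told apart from a shared response. Since edgeR called features against water after silver dihydrogen citrate only, its calls could not overlap. DESeq2 called lmos81, lmos84, lmo0189, lmo1665 and qoxB higher, and limma-voom lmo0783 lower, both after lactic acid and after silver dihydrogen citrate, against the same water libraries.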

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

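The tests chosen only after the result was seen were all those on features lower after silver dihydrogen citrate, the chance test of features shared by lactic acid and silver dihydrogen citrate and the fragment class test of lmos81 itself, the test of the 16S entry itself within short-fragment libraries, those of the summed 16S CPM, and the counts at an unadjusted p over the splits; the spread condition on the summed 16S share was also set afterwards.

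After silver dihydrogen citrate the features lmos55, lmo0646 and lmo1423 fell, with a median log2 fold change of −6.62 (median standard error 1.12) against water. With library totals in place of TMM factors none of them was called. The TMM factor of silver dihydrogen citrate replicate 1 was 8.82. A part played by the scaling was not tested and stays open. Shallow coding depth of silver dihydrogen citrate replicates 3 and 4 is argued against as the whole cause, since the median without them was −6.30 (median standard error 1.61). However, lmos55 alone was then still called (0 counts left after silver dihydrogen citrate, at least 409-fold lower, adjusted p = 1.75e-09). There lmo0646 stood at −6.30 ± 1.73 (adjusted p = 0.0590) and lmo1423 at −2.92 ± 1.01 (adjusted p = 0.437). A loss of short features from libraries with longer fragments was examined over the 37 tested features under 100 bases. Their median lay 1.13 above that of longer ones, so no general loss of short features was seen. These may be largely transfer RNAs, of which 34 were tested, with a median of 1.07. Transfer RNAs may move unlike other short RNAs, so such a loss stays open for lmos55 (79 bases). It does not apply to lmo0646 (840 bases) and lmo1423 (831 bases). With the fragment length class as a term the median was −4.00 (median standard error 1.53) and the calls ended. Standard errors grew, and the folds of lmos55 and lmo0646 shrank. The fold of lmo1423 was −3.83 ± 0.94 before and −4.00 ± 1.11 after, and that of lmos55 −6.62 ± 1.12 and −5.34 ± 1.53. Both stayed more than 2 standard errors below 0, which restates edgeR's test before adjustment. In long-fragment libraries alone, with 1 water library, lmo1423 stood at −4.02 ± 1.39, so the class is argued against as its whole cause. There lmos55 stood at −3.23 ± 1.81. That water library held lmos55 at 4.36 CPM, against 21.7 to 65.4 CPM in the other water libraries, so the class stays open for lmos55. For lmo0646 (−6.72 ± 1.48 before, −3.14 ± 4.50 after) the class cannot be told apart from the treatment, since the only long-fragment water library has 0 counts of it (against peracetic acid it stood at −5.55 ± 1.45 with the class as a term). An effect of silver on these transcripts stays open.

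The RNA lmos81 was higher in all 8 lactic acid and silver dihydrogen citrate libraries (6763 to 40933 CPM) than in the other 10 (1965 to 4347 CPM), the 1 feature of 80 at 10 or more CPM after TMM scaling to separate them; the pattern was first noticed in lmos81, lmos84 and lmo0189 against water and peracetic acid only. Chance is not excluded, because these 8 libraries were picked after features were seen to separate them, so that the real choice being the 1 choice to separate as many features, with 0 as the highest of 100 random choices, restates the observation. Normalization could produce the separation, because by library totals 0% of the separating features still separated (water replicate 4 at 0.672% and silver dihydrogen citrate replicate 3 at 0.669% of all counts), whereas scaling by coding counts kept 1 of 1. For lmos81 the fragment length class is argued against, since the other 4 long-fragment libraries (1965 to 3768 CPM) lay at most 0.118 of the way from the short-fragment libraries (2420 to 4347 CPM) to the lactic acid and silver dihydrogen citrate ones. Over the 4 features, lmos81 among them, that separate the short-fragment libraries from those 8, the class cannot be told apart, because the median position of 0.315 covers −0.0804 to 0.771, and a response common to the sanitizers stays open and untested.

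The 16S entry lmor04 was lower in both chlorine libraries (23.5 ± 1.02 CPM) than in all others. The fragment length class is argued against for the entry itself, which stood at −4.38 ± 0.62 within short-fragment libraries (adjusted p = 3.84e-09). With TMM factors, the scale of the entry, the 5 near-identical 16S entries were summed. The chlorine libraries (103 and 111 CPM) lay below all others (166 to 1751 CPM). The log2 gap was 0.578, also to the short-fragment ones, and the chlorine SD 0.0821. This goes against reads shared between the copies, and against the class, as the whole cause. It excludes neither, since that SD rests on 2 libraries and the gap is small beside the spread of the others. The sum also holds the entry, which made up most of it in all other libraries but water replicate 4. As a share of all counts neither can be told apart from a lower 16S level, since 16 of the 16 other libraries, and all 4 short-fragment ones among them, lay above both chlorine libraries, but by a gap of 0.301 that was below the chlorine SD of 0.802. The entry took 21.8 to 22.2% of the 16S counts in the chlorine libraries and 29.8 to 96.6% elsewhere, so a different assignment of reads among the copies could contribute, and a difference in ribosomal RNA or in its depletion after chlorine stays open and untested, with 2 libraries in the group.

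Other divisions of the same libraries were counted for each comparison of 4 against 4. Between peracetic acid and silver dihydrogen citrate 1 of the 35 splits, the real one, gave 5 features, and the highest other gave 1. This is the smallest share that 35 splits can give, and it was the best of several comparisons, so chance is not excluded. At an unadjusted p under 0.05 the real count was 174 and the highest other 172. Between silver dihydrogen citrate and water 2 of the 35 splits gave 3 features, the real one and the one that puts silver dihydrogen citrate replicate 3 with water replicates 1 to 3, so chance is not excluded, nor for the 196 features at an unadjusted p under 0.05, which 2 of the splits reached; that split keeps the 3 short-fragment water libraries together, and with the class as a term 0 features were called by edgeR (103 at an unadjusted p under 0.05; DESeq2 and limma-voom were not run with that term). For lactic acid against water, peracetic acid against water, lactic acid against peracetic acid and lactic acid against silver dihydrogen citrate the real split gave 0 features by edgeR, so all 35 of the 35 splits had to give as many, which says nothing about chance; the highest others gave 1, 0, 0 and 2. The counts at an unadjusted p under 0.05 in these comparisons were 237, 145, 207 and 183, which 2, 26, 2 and 3 of the 35 splits reached, the real one included (highest others 247, 182, 209 and 224), so chance is not excluded for these counts. DESeq2 called 13, 0, 2 and 9, and limma-voom 5, 0, 1 and 0.

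Of 52 groups of 4 libraries examined, 9 held 1 library far from the others, where chance gives about 1 in 20 groups, or 2.6. That rate holds only roughly here. Where all others had 0 the gap fills the range by construction, and lmos81 in 1 library was counted both as share and as CPM. In silver dihydrogen citrate replicate 3, coding features made up 2.04% of the counts outside lmos95 and lmos89, against 7.45 to 8.07% in the other silver dihydrogen citrate libraries. In silver dihydrogen citrate replicate 1, lmos81 took 36.0% of the counts, against 0.669 to 3.14%. The same library had lmos81 at 40933 CPM, against 6763 to 11135 CPM. It also had lmo0646 at 0.232 CPM, with 0 in the other silver dihydrogen citrate libraries. Silver dihydrogen citrate replicate 3 had lmos55 at 1.998 CPM, with 0 in the others. Peracetic acid replicate 2 had 1385 coding features with counts, against 904 to 985. Water replicate 3 had 1276 CPM over the 16S entries, against 166 to 340 CPM. Lactic acid replicate 1 had lmo0646 at 11.7 CPM, against 0 to 0.702 CPM, and lmor04 at 564 CPM, against 754 to 765 CPM.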

How the results depend on the processing

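The settings chosen after the data were seen are the fragment length class as a term, libraries of 1 class only, coding features only and libraries with at least 10000 coding counts only; for the results that changed, the cause was not tested. The low coding counts are a limit, with a median of 2 counts per library over the tested features. Of 2915 values of named features under other settings (222 results), 2773 kept their sign and side of the threshold. Another 30 passed only under the other setting, and 7 no longer passed. The remaining values had the other sign with no call, spread over 51 of the results, and 0 called values reversed. Most of the 222 results were not called in the edgeR fit of all libraries, and at low power such a result tends to stay uncalled. The 2773 values therefore do not measure how stable the calls were. Only called results could stop passing, so the 7 values come from these few. Features changed by chlorine numbered 0 and became 1 without a filter on low counts, in a fit of the groups compared, in short-fragment libraries and with at least 10000 coding counts (lmor04 each time), and 2 by DESeq2 and limma-voom. Lactic acid went from 0 to 1 at 10 or more CPM (a filter on unscaled CPM), 13 by DESeq2 and 5 by limma-voom. Peracetic acid went from 0 to 2 in short-fragment libraries, of which 1 is from peracetic acid. Silver dihydrogen citrate went from 3 to 10 with library totals, 9 at 10 or more CPM, 32 by DESeq2, 29 by limma-voom, 7 with at least 10000 coding counts, and 0 with the class as a term and in long-fragment libraries. Chlorine against lactic acid went from 1 to 0 at 10 or more CPM and without the 10 most abundant features, and to 4 by DESeq2 and in a fit of the groups compared. Chlorine against peracetic acid went from 1 to 0 with RLE factors, at 10 or more CPM and without the 10 most abundant features, to 2 by DESeq2 and to 4 in a fit of the groups compared. In the last pair of comparisons the call was lmor04, itself 1 of the 10 most abundant features, so its loss without them was fixed by the setting. Chlorine against silver dihydrogen citrate went from 3 to 7 at 10 or more CPM, 15 by DESeq2 and 9 by limma-voom. Lactic acid against peracetic acid went from 0 to 1 at 10 or more CPM, by limma-voom and in a fit of the groups compared, and to 2 by DESeq2. Lactic acid against silver dihydrogen citrate went from 0 to 6 with library totals and 9 by DESeq2. With the class as a term the comparisons of chlorine with lactic acid, peracetic acid and silver dihydrogen citrate went to 0 by edgeR (73, 25 and 61 at an unadjusted p under 0.05), and peracetic acid against silver dihydrogen citrate stayed at 5. Peracetic acid against silver dihydrogen citrate went from 5 to 1 without a filter, 14 at 10 or more CPM, 29 by DESeq2 and 9 by limma-voom. The gene list calls went from 1 to 0 with an estimated correlation and by fry, and to 2 with RLE factors.

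Leaving out each library in turn gave 0 to 1 features for chlorine (1 without water replicate 4), 0 to 0 for lactic acid and for peracetic acid, and 2 to 10 for silver dihydrogen citrate (10 without its replicate 1, 5 without replicate 2, 7 without replicate 3, and 2 without its replicate 4, water replicate 2 or water replicate 4). Chlorine against lactic acid and against peracetic acid gave 0 to 1 (0 without either chlorine library, where the lone library is assumed to vary like the other groups). Chlorine against silver dihydrogen citrate gave 0 to 5 (0 without chlorine replicate 1, 2 without chlorine replicate 2, 5 without silver dihydrogen citrate replicate 1 or 3). Lactic acid against peracetic acid gave 0 to 0, and lactic acid against silver dihydrogen citrate 0 to 1 (1 without silver dihydrogen citrate replicate 3). Peracetic acid against silver dihydrogen citrate gave 1 to 10 (2 without peracetic acid replicate 1, 3 or 4 or silver dihydrogen citrate replicate 3, 1 without peracetic acid replicate 2 or silver dihydrogen citrate replicate 4, 10 without silver dihydrogen citrate replicate 1). The log2 fold change of lmo1423 by silver dihydrogen citrate was −3.70 without water replicate 2, −3.72 without water replicate 4 and −3.45 without silver dihydrogen citrate replicate 4, none of them called.

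The correlations between sanitizers changed when the water libraries were split and at 10 or more CPM. For shared responses between sanitizers: chlorine and lactic acid went from 0.402 to −0.0118 and −0.0415 (0.300 to 0.535 with libraries left out in turn). For shared responses between sanitizers: chlorine and peracetic acid went from 0.487 to −0.0227 and −0.236 (0.333 to 0.627). For shared responses between sanitizers: chlorine and silver dihydrogen citrate went from 0.433 to −0.0201 and −0.0296 (0.311 to 0.567). The shared responses between sanitizers: lactic acid and peracetic acid went from 0.484 to 0.0282 and 0.422 (0.424 to 0.605). The shared responses between sanitizers: lactic acid and silver dihydrogen citrate went from 0.530 to 0.0994 and 0.638 (0.465 to 0.617). The shared responses between sanitizers: peracetic acid and silver dihydrogen citrate went from 0.519 to 0.0184 and 0.334 (0.442 to 0.641). Splitting the water libraries removes the controls that the fold changes otherwise share, but not a difference between the fragment length classes.

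The replicate numbers showed little pairing of the libraries: 32 same-numbered pairs had a median correlation of deviations of 0.0186 (−0.156 to 0.139), and 2 lay above 0.1. The median of other pairs was 0.000254, and 9 of 18 libraries correlated best with their own number, so weak pairing stays open. With the replicate number as a block, 0 features were called for chlorine (26 at an unadjusted p under 0.05), 0 for lactic acid (124), 0 for peracetic acid (56) and 6 for silver dihydrogen citrate. The block gave 1, 1 and 4 features for chlorine against lactic acid, peracetic acid and silver dihydrogen citrate, 0 (111) for lactic acid against peracetic acid, 0 (86) against silver dihydrogen citrate, 4 for peracetic acid against silver dihydrogen citrate, and 1 gene list.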

Other observations

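The values here were singled out after the data were seen, and no test was added for them. The small RNA lmos55 lies between the ribosomal protein gene rplU and lmo1543. The gene rplU stood at −2.63 ± 0.91 after silver dihydrogen citrate (4.06 ± 5.13 against 25.8 ± 6.78 CPM in water, n = 4 each, adjusted p = 0.238) and at −2.08 ± 0.90 after lactic acid (adjusted p = 0.270), and at −0.07 after peracetic acid and −0.54 after chlorine. For silver dihydrogen citrate it was called with features at 10 or more CPM (−2.87, adjusted p = 0.0302), by DESeq2 (−2.76, adjusted p = 0.00453) and without silver dihydrogen citrate replicate 1 (−3.92, adjusted p = 0.0268).

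The features lmo0189 and lmos84 had their highest group means after silver dihydrogen citrate and lactic acid. The level of lmo0189 was 7.33 ± 1.51 CPM in water, 31.5 ± 8.53 after lactic acid, 45.4 ± 22.7 after silver dihydrogen citrate, 17.1 ± 12.01 after peracetic acid (n = 4 each) and 6.94 ± 6.06 after chlorine (n = 2). The level of lmos84, which overlaps lmo2257 and is uncertain for that reason, was 24.4 ± 16.8 CPM in water, 80.1 ± 25.8 after lactic acid, 86.3 ± 63.1 after silver dihydrogen citrate, 15.4 ± 3.32 after peracetic acid and 17.3 ± 1.45 after chlorine. In the edgeR fit of all libraries neither was called against water. For silver dihydrogen citrate, edgeR called lmo0189 with library totals (4.92), with features at 10 or more CPM (2.55), without replicate 3 (2.93) and with at least 10000 coding counts (3.09), and lmos84 with library totals (4.63). DESeq2 called both for lactic acid (lmo0189 at 2.61, lmos84 at 2.17) and for silver dihydrogen citrate (2.85 and 2.02).

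Among features that averaged 10 or more CPM after TMM scaling, 12 of 80 lay below every water library in all 4 silver dihydrogen citrate libraries and 2 above, where chance gives 2.29 over both directions together. The counts were 5 below and 4 above for lactic acid, 0 and 0 for peracetic acid, and 5 and 0 for chlorine, where chance gives 10.7 over both directions with 2 libraries. The features share the same libraries and are not independent, and the chance values carry no spread. All silver dihydrogen citrate libraries have long fragments and water replicates 1 to 3 short ones. Silver dihydrogen citrate replicates 3 and 4 hold 3639 and 5454 coding counts. With library totals the silver dihydrogen citrate calls were higher rather than lower, so the direction may rest on the scaling.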
